A study of Homo sapiens with 29 samples.

How the data were processed

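Poly(A) RNA was sequenced from human B cells of peripheral blood leukocytes (concentration libraries) and from human CD4+ T cells (storage and cryopreservation libraries). The authors deposited 3 tables of whole-number read counts per gene, with no normalization, and the values summed to different totals in each column. Libraries were made with standard Illumina protocols, per the labels' protocols. The submitters' processing notes name FastQC, HISAT2 2.0.4, MultiQC and the GRCh38 genome build, without versions for the others. The counting program, its gene annotation and its handling of strand and of reads with several matches were not given in the sources used here. Counts of near-identical gene copies, pseudogenes, overlapping genes and antisense genes are therefore uncertain, since reads could be divided between them by the aligner or the counting program.

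Each table held 60542 gene identifiers, of which 41613 were given a symbol from a gene name table and 56937 (94.05%) were found in GENCODE release 29, which supplied positions and gene types. Of 29 samples, 27 had a count column that was used. The concentration table held 8 columns, and 6 were matched to a labelled concentration. Its columns of per-sample values not matched to a sample numbered 2, those for 250, and were left out. The labels gave 1 sample at 250 and gave a pair of samples at 100 titles that differed only by a space. Column names in that table carried a letter instead of a replicate number, and the letter was not explained in the sources used here. The suffixes SR, FR, SRN and f were not spelled out either and were used as plain group names. In the storage and cryopreservation tables, the shared number in the titles defined the pairs.

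Pairing was checked before calls were compared. Deviations of same-numbered libraries from their group means correlated at 0.555 to 0.753 in the 6 storage pairs and at 0.378 to 0.683 in the 4 cryopreservation pairs, all above the limit of 0.1. Of 45 pairs of libraries from 1 group, none held identical values, and the chi-square statistic per gene ran from 9.06 to 184.2, far above sampling noise. No library was therefore taken as the same library sequenced again. Separate libraries made from 1 RNA sample could also exceed that noise and were not excluded. The pairs at concentrations 1, 100 and 500 had the lowest values, 11.7, 9.06 and 16.2.

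Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the default expression filter, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment at 0.05. The contrasts were 1 minus 500, 100 minus 500 and 1 minus 100, a slope on log10 concentration, SR minus FR, and f minus no suffix. These tests carried no replicate term, and a fit with the pair number as a block was run beside them. Values are CPM scaled by TMM, given as mean ± SD. Sums over gene families used library totals instead. So did the cytokine and olfactory receptor sums and the comparison of B cell genes with their level in the B cell libraries. The log2 changes carry a standard error (SE) equal to the change divided by the square root of the quasi-likelihood F. Other settings chosen beforehand were DESeq2 1.42.0, limma-voom in limma 3.58.1, DESeq2 size factors or library size alone within edgeR, no filter, a mean count of at least 50, an absolute log2 change of at least 1, thinning of every library to the lowest total of its table, and leaving out each library or pair in turn. Simulations with no change were run without and with the letter, and group means were recomputed without each library. After the data were seen, the column letter as a batch term and a restriction to protein-coding genes were added.

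The 32 gene lists covering cell types, cell states, stress, metabolism, RNA classes and housekeeping functions were fixed before the data were examined, and a list needed 3 tested members. Lists were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), with camera using an estimated correlation and with fry. The concentration and cryopreservation comparisons tested 31 lists and the storage comparison 30, the others having too few tested members. Genes named in the text were chosen by a rule fixed before the data were examined. It took the 10 genes with the highest absolute log2 change in each direction among those called, with a symbol, an average log2 CPM of at least 1, and an identical direction in every pair or no overlap between the groups. Free places were filled from the blocked fit (the letter fit, added later, for concentration), and the 4 members with the lowest p of each list past the threshold were added, up to 30 genes per contrast. Immunoglobulin and T cell receptor segments were never named, and a few other genes are not reported here.

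Library measures were compared with exact two-sided permutation tests over library labels, with Benjamini-Hochberg adjustment over 6 measures. Depth per library set a floor, taken as 3 counts, of 0.0688 to 0.151 CPM over the storage libraries, 0.0874 to 0.119 CPM over the cryopreservation libraries and 0.0769 to 0.125 CPM over the concentration libraries. Such floors and all counting intervals cover counting error only. The pipeline was tested on simulated counts with 200 changed genes, all drawn from genes with a mean count of at least 50. The shares of changed genes called therefore do not cover tested genes with lower counts. At a log2 change of 1 it called 83.6% of the changed genes for concentration 1 against 500 (91.0% with the letter), 76.1% for SR against FR (100% with the block) and 38.8% for f against no suffix (86.6% with the block). At a log2 change of 0.5 these shares were 44.8% (62.7%), 32.8% (80.6%) and 1.49% (32.8%). Unchanged genes made up 14.7% (12.4%), 0.719% (6.03%) and 9.28% (9.32%) of the calls, above the nominal 5% in every fit but SR against FR without the block. Summaries and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.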

Results

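Gene counts were analysed for human blood lymphocytes whose RNA had been handled in different ways, in a study of RNA concentration, of how long libraries were stored and of cryopreservation. The concentration libraries came from B cells and were labelled 1, 100 or 500, with 2 libraries used at each and no unit given. The storage libraries came from CD4+ T cells and were marked SR (n = 6) or FR (n = 6), plus 1 library marked SRN. The cryopreservation libraries also came from CD4+ T cells, 4 with the suffix f and 4 without it. Counts assigned to genes totalled 24.0 to 39.0 M per concentration library, 19.9 to 43.6 M per storage library and 25.2 to 34.3 M per cryopreservation library. The sources used here did not say whether libraries of 1 group came from separate donors, so the p-values measure the spread between these libraries.

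In B cell libraries labelled 1 and 500, the fit without a batch term called 2 pseudogenes, a noncoding RNA, a multi-copy gene and NUDT4. F8A2 (ENSG00000274791, chromosome X, 155382115 to 155383230), one of several near-identical copies of a gene for a huntingtin-associated protein, was at 0.0385 ± 0.00461 CPM at 1, 0.0527 ± 0.0746 at 100 and 16.9 ± 4.29 at 500 (SD, n = 2 each). GRAPLDR (chromosome 17, 19160789 to 19162274), a long noncoding RNA, was at 0.119 ± 0.0683, 0.0352 ± 0.0497 and 6.86 ± 1.04 CPM at 1, 100 and 500. SNX29P2, a pseudogene of the sorting nexin gene SNX29, was at 0.364 ± 0.0166, 0.269 ± 0.281 and 6.81 ± 0.655 CPM. RPL21P134, a pseudogene of a ribosomal protein gene, was at 0.734 ± 0.439, 0.302 ± 0.0199 and 9.62 ± 1.14 CPM. NUDT4 (ENSG00000173598, chromosome 12, 93377883 to 93408146), a phosphatase acting on inositol pyrophosphates, went the other way, at 142 ± 8.21 CPM at 1, 141 ± 5.03 at 100 and 90.0 ± 4.74 at 500.

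In edgeR these were the 5 genes of 18582 tested that differed between 1 and 500, 1 higher and 4 lower at 1. NUDT4 was higher by 0.66 log2 units (SE 0.06, adjusted p = 0.0113), and the adjusted p-values of F8A2, GRAPLDR, RPL21P134 and SNX29P2 were 0.000587, 0.00372, 0.00741 and 0.0215. In limma-voom F8A2, GRAPLDR and SNX29P2 were not called. In edgeR SNX29P2 lost its call without either library at 1 or without the one with column letter d at 500, and NUDT4 without the one with letter d at 1. F8A2 had 2 counts over both libraries at 1 and 3 at 100 against 1311 at 500, CPM ratios of 0.227% (95% exact interval 0.0275% to 0.822%) and 0.317% (0.0653% to 0.929%). Between 100 and 500, 6 genes differed (2 higher, 4 lower), and the same 5 genes were among them, with NUDT4 higher by 0.65 (SE 0.06, edgeR adjusted p = 0.0128). Here limma-voom did not call F8A2 or SNX29P2, and edgeR did not call NUDT4 without the library with letter c at 500 or letter d at 100. The other call, ENSG00000204745, an unprocessed pseudogene without a symbol that was chosen after its values were seen, was at 6.37 ± 0.0406 CPM at 100 and 2.22 ± 0.0608 at 500 (edgeR adjusted p = 0.0458).

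Summed over the annotated copies and scaled by library totals, F8A genes were at 11.9 ± 8.02 CPM at 1, 8.17 ± 2.65 at 100 and 25.3 ± 1.95 at 500 (n = 2 each), so the sum differed far less than F8A2 did. F8A1 alone was at 11.4 ± 8.07, 7.48 ± 3.12 and 7.65 ± 1.79 CPM. The RPL21 family of 134 loci summed to 736 ± 20.1, 676 ± 13.9 and 697 ± 9.93 CPM. SNX29 with its pseudogenes summed to 259 ± 2.96, 266 ± 3.24 and 276 ± 3.39 CPM. GRAP, GRAPL and GRAPLDR summed to 17.7 ± 1.06, 19.0 ± 0.343 and 31.8 ± 2.70 CPM, so here the sum was higher at 500 too. NUDT4 with its copies was at 142 ± 8.55 CPM at 1 and 89.7 ± 5.38 at 500, which left its difference in place. Between 1 and 100, edgeR called 0 genes, with 615 at an unadjusted p under 0.05, while DESeq2 called 5 and limma-voom 0. In the test for a slope on log10 concentration edgeR called 1 gene, F8A2 (adjusted p = 0.00669), but its levels at 1 and 100 were both near 0, so the difference lay between 100 and 500 and no slope is given. Neither DESeq2 nor limma-voom called F8A2 in that test.

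Without a batch term, a count this low is within what chance gives at 2 libraries per group. The simulations below compared numbers of calls, and the size of the changes was not set against them. In 40 simulations with no change and no letter effect, edgeR called 5 genes on average between 1 and 500, 5 or more in 22 of them and up to 16. The 5 genes shared by both comparisons with the 500 libraries stood against a simulated mean of 1.45 (highest 5, reached in 1 simulation), and independent lists would share 0.000108 genes higher and 0.000861 lower. Both comparisons shared the libraries at 500 in the simulations too, so the mean of 1.45 already includes that sharing. With only 2 libraries at 500 the shared controls could not be split. A difference of these libraries apart from their concentration was therefore not told apart from concentration. Totals at 500 (38.9 M on average) were above those at 1 (26.1 M) and 100 (28.1 M), and edgeR still called 5 genes for 1 against 500 after thinning.

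**Figure D1:**
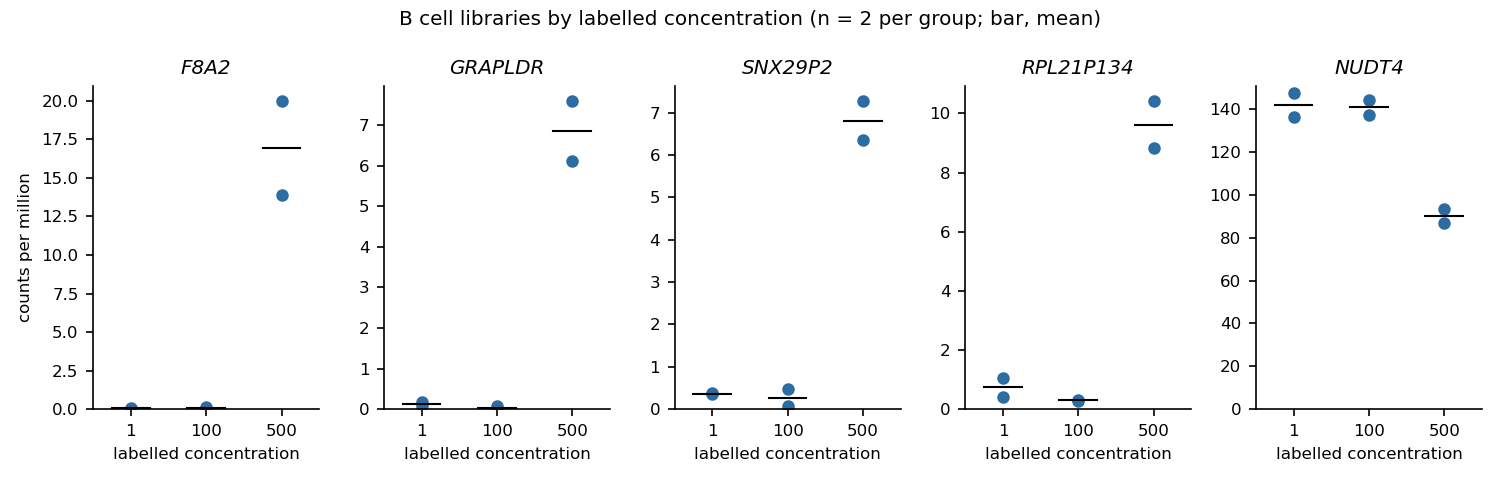
CPM (vertical axis, starting at 0) of the 5 genes called between concentrations 1 and 500, by labelled concentration (horizontal axis, unit not given); points are the 2 libraries of each group and bars their means. F8A2 lies at or below 0.106 at 1 and 100 and at 13.9 and 19.97 at 500, while NUDT4 lies above 136 at 1 and 100 and below 93.4 at 500.

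With the column letter added as a batch term, an alternative chosen after the data were seen, edgeR called 133 genes between 1 and 500 (93 higher, 40 lower at 1). The biological coefficient of variation went from 9.28% to 5.06%. In 40 simulations with no change between concentrations and the letter effect kept, this fit called 9.28 genes on average and at most 21. Of the 133 calls, 116 (87.2%) were protein coding, against 68.95% of the tested genes (Fisher's exact p = 1.15e-06 across genes, which are not independent replicates), and 9 (6.77%) were pseudogenes, against 11.29%. Among genes higher at 1 in that fit were DNAJB9, a chaperone of the endoplasmic reticulum, at 26.9 ± 0.0266 against 20.1 ± 0.0357 CPM (SD, n = 2; log2 change 0.42, SE 0.08, edgeR adjusted p = 0.0396), and GABPA, an ETS transcription factor, at 94.5 ± 4.66 against 73.1 ± 4.05 CPM (0.37, edgeR adjusted p = 0.0108). TWF1, an actin-binding protein, and RPL9 rose by 0.41 and 0.42. The ribosomal protein pseudogenes RPL21P28, RPS28P4 and RPL21P116 and the multi-copy gene SRGAP2B were also higher at 1, with log2 changes of 5.49, 1.44, 0.66 and 1.03. Summed with its copies and scaled by library totals, however, SRGAP2 was at 64.8 ± 5.91 CPM at 1 and 63.2 ± 0.247 at 500. Genes lower at 1 included TXNDC5, a disulfide isomerase of the endoplasmic reticulum, at 16.3 ± 4.47 against 23.7 ± 5.90 CPM (-0.54, edgeR adjusted p = 0.0178), SIAH2, a ubiquitin ligase (-0.32), LY6E (-0.24), PDXP (-0.94) and the pseudogene PDPK2P (-1.58). BOLA2B, 1 of a pair of identical copies, was at 0.0418 ± 0.0591 against 6.37 ± 3.196 CPM, and its copy BOLA2 was listed at 0 in every group. Scaled by library totals, the 2 libraries at 100 were at 0.0707 and 5.49 CPM for BOLA2B. For RPL21P28 they were at 0.789 and 20.7 CPM, so both copies also differed between libraries of 1 concentration. Without the letter term each gene named here from the letter fit had an edgeR adjusted p of 0.83. With no filter and no letter, edgeR called RPL21P28, RPS28P4, SRGAP2B, RPL21P116, RPL9, GABPA, BOLA2B and PDPK2P. DESeq2 called RPS28P4, RPL21P116, GABPA and PDPK2P. RPS28P4 and RPL9 were called without the library with letter d at 1, and RPL21P28 and BOLA2B without either library at 100.

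Gene groups moved little with concentration in B cells. All 13 protein-coding genes of the mitochondrial genome had log2 changes below 0 at 1 against 500 (median -0.14, camera adjusted p = 8.8e-07). MT-ND4 was at 5356 ± 198 against 6029 ± 142 CPM and MT-CYB at 3298 ± 36.5 against 3643 ± 217 CPM. Ribosomal protein genes had a median of -0.04 over 77 members (camera adjusted p = 0.00124), among them RPLP1 (-0.14), RPLP2 (-0.12) and RPS15 (-0.15). Splicing factors had a median of +0.06 over 24 members (camera adjusted p = 0.00124), among them SRSF2 (0.13), PNISR (0.12) and SRSF11 (0.09). For all 3 lists the adjusted p = 0.948 with an estimated correlation. No member of these lists was called by edgeR over all genes or when adjusted over the list alone. In the letter fit 3 of 13 mitochondrial genes fell and 10 fell when adjusted over the list alone. Genes that mark B cells (22 tested, among them MS4A1 and BANK1) had a median of -0.07 (camera adjusted p = 0.115; adjusted p = 0.948 with an estimated correlation). In the letter fit that list passed camera (adjusted p = 0.00487; adjusted p = 0.953 with an estimated correlation), and 1 member fell over all genes and 12 when adjusted over the list alone, where 3 rose. The share of counts on the mitochondrial genome was 3.95% ± 0.204 at 1, 4.18% ± 0.368 at 100 and 4.38% ± 0.214 at 500 (n = 2 each). Mitochondrial and ribosomal lists were also lower at 100 than at 500 (medians -0.08 and -0.03, camera adjusted p = 0.00918 and 0.00625; adjusted p = 0.991 with an estimated correlation). The mitochondrial list was lower at 1 than at 100 (median -0.07, camera adjusted p = 0.0192; adjusted p = 0.983 with an estimated correlation).

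In CD4+ T cells, libraries marked SR differed from those marked FR in many pseudogenes, genomic copies of other genes, which made up most calls without the pair block and 48.1% of them with it. TECRP1, a copy of the gene for a fatty acid elongation enzyme, was at 5.79 ± 2.19 CPM in SR and 0.906 ± 0.445 in FR (SD, n = 6 each; log2 change 2.68, SE 0.34, edgeR adjusted p = 0.00176). BZW1P2 was at 8.43 ± 1.82 against 1.37 ± 0.636 CPM (2.61, SE 0.28, edgeR adjusted p = 0.000551). IFNG, the gene of the cytokine interferon gamma, fell to 1.25 ± 0.138 CPM in SR from 2.95 ± 0.523 in FR (log2 change -1.24, SE 0.16, edgeR adjusted p = 0.00221), in 6 of 6 pairs. NUS1, a subunit of the enzyme that makes dolichol, fell by 0.67 on the log2 scale, from 78.0 ± 10.1 to 49.1 ± 7.34 CPM (SE 0.11, edgeR adjusted p = 0.00921).

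Of 18461 genes tested, edgeR called 88, of which 69 were higher and 19 lower in SR. Pseudogenes made up 73 of the 88 calls (82.95%) against 10.45% of the tested genes (Fisher's exact p = 4.9e-57 across genes, which are not independent replicates). The share of all counts on pseudogenes differed little, at 2.03% ± 0.135 in SR and 1.95% ± 0.147 in FR. It was higher in SR in 4 of 6 pairs (exact permutation p = 0.392 unpaired and 0.125 paired, both unadjusted). Also higher in SR were RAC1P2, PHC1P1, RPL35P1, EIF3LP2, EEF1B2P6, SUCLG2P2 and PAIP1P2, with log2 changes of 2.04, 1.84, 1.79, 2.05, 1.64, 1.44 and 1.39, each in 6 of 6 pairs. Pseudogenes lower in SR were BTF3P3 (-1.55), RPS27AP12 (-1.25), RPL7P32 (-1.01) and RPS6P25 (-0.81), again in every pair. MRPL23, a protein of the mitochondrial ribosome, fell from 11.1 ± 3.79 to 4.40 ± 0.757 CPM (-1.33, SE 0.21, edgeR adjusted p = 0.00921). Without the block, EEF1B2P6 lost its call when any pair but 6 was left out, SUCLG2P2 any but 3, RPS27AP12 any but 5 and RPS6P25 any but 2. RPL7P32 lost it without pair 3 or 5, NUS1 without pair 1 or 5, and MRPL23 without pair 6 and among protein-coding genes alone. At a mean count of at least 50 SUCLG2P2 and RPS27AP12 were not called, and SUCLG2P2 was not called after thinning.

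The remaining protein-coding calls were chosen after their values were seen and were low or are themselves copies of other genes. Higher in SR were UQCRHL (1.24), MMP23B (2.98), PPP1R2B (1.41), ARL6IP4 (0.90) and ENSG00000230626 (2.36), and PGAM4 was lower (-1.40). Together with IFNG, NUS1 and MRPL23 these were the 9 protein-coding genes called, out of 13163 tested.

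**Figure D2:**
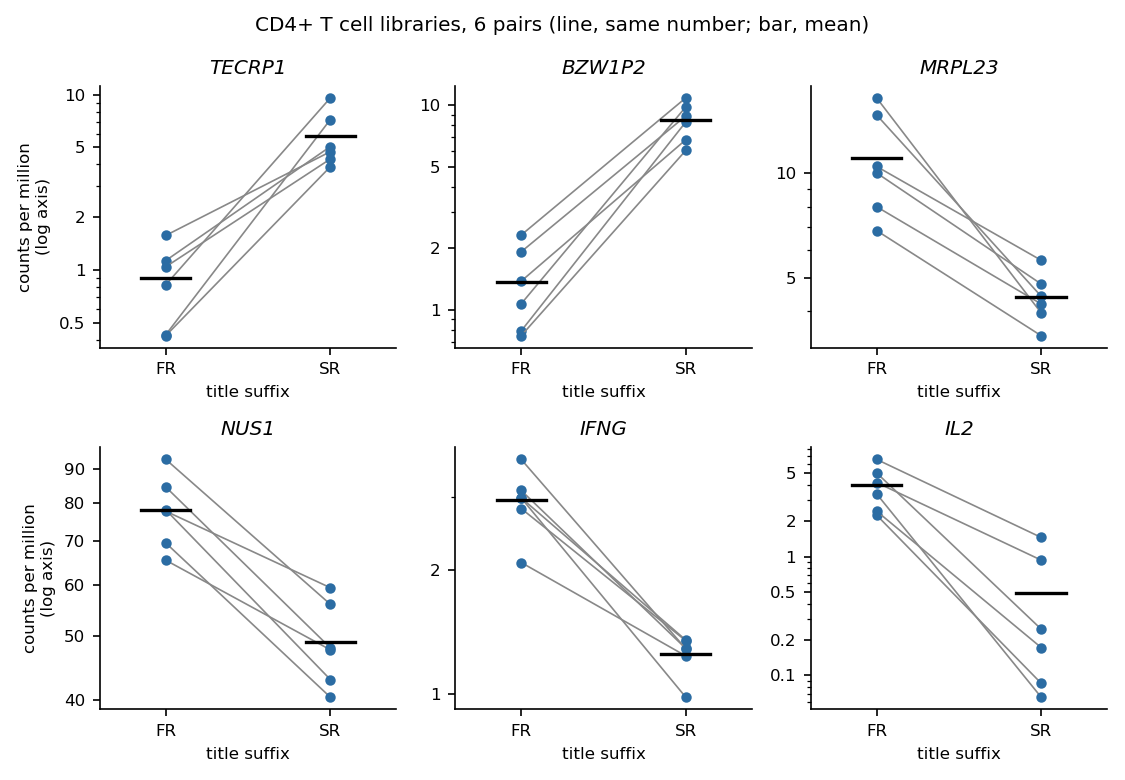
CPM (vertical log axes) of 6 genes in CD4+ T cell libraries marked FR and SR (horizontal axis); each line joins the FR and SR library with the same number (6 pairs) and thick bars are means. TECRP1 and BZW1P2 are higher in SR in every pair, and MRPL23, NUS1, IFNG and IL2 are lower in SR in every pair.

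Blocking on the pair raised the count to 443 genes (247 higher, 196 lower in SR), of which 213 (48.1%) were pseudogenes. These were mostly higher in SR (150 higher, 63 lower), while the 187 protein-coding calls were mostly lower (62 higher, 125 lower). The biological coefficient of variation went from 28.2% to 5.17%. IL2, the gene of the T cell growth factor interleukin 2, was at 0.492 ± 0.569 CPM in SR and 3.97 ± 1.66 in FR, lower in SR in 6 of 6 pairs (edgeR adjusted p = 0.0524 without and 1.92e-06 with the block; blocked log2 change -3.24, SE 0.29). Without SR replicate 5 the SR mean of IL2 was 0.300 CPM. The pseudogenes EEF1A1P4 (3.93 ± 5.65 against 34.1 ± 20 CPM) and RPL29P26 (2.11 ± 2.98 against 14.2 ± 2.02 CPM) were likewise not called in the unblocked fit and called with the block (blocked log2 changes -3.22 and -2.93, edgeR adjusted p = 0.000393 and 3.79e-05). Their SR means were 1.63 CPM without SR replicate 6 and 0.896 CPM without SR replicate 4. In other fits without the block, IL2 was called in DESeq2, in limma-voom, with no filter and without pair 5. EEF1A1P4 was called in DESeq2 and without pair 6, and RPL29P26 in limma-voom, with no filter, after thinning and without pair 4.

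Among gene groups, the T cell activation list (15 tested) was lower in SR (median log2 change -0.06, mean -0.37, camera adjusted p = 0.000222), but adjusted p = 0.301 with an estimated correlation. Of its members 1 fell (IFNG), 0 rose, and 2 fell when adjusted over the list alone, and with the block 4 fell (IFNG, IL2, IRF4 and EGR2). IRF4, a transcription factor of activated lymphocytes, was at 34.2 ± 6.38 CPM in SR and 38.7 ± 7.07 in FR (blocked log2 change -0.18, SE 0.03, edgeR adjusted p = 0.00766). TNFRSF9, a costimulatory receptor, was at 2.05 ± 0.338 and 2.81 ± 1.02 CPM (blocked edgeR adjusted p = 0.317). T cell identity genes such as CD3E and CD28 (22 tested) had a median of -0.01 (camera adjusted p = 0.979) and B cell genes (15 tested) also -0.01 (camera adjusted p = 0.979). Of 30 lists tested, the other 29 did not pass the threshold without the block. With the block 7 lists passed camera, all with small medians. T cell activation (blocked median -0.056, adjusted p = 0.000304), immediate early (-0.015, 0.0308) and glycolysis genes (-0.028, 0.0329) were lower in SR. Mitochondrial genome (0.020, 0.00854), ribosomal protein (0.011, 0.0308), nuclear long noncoding RNA (0.022, 0.00854) and splicing genes (0.009, 0.0308) were higher. For these 7 the adjusted p = 0.286 to 0.503 with an estimated correlation.

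Scaled by library totals, parent genes of several pseudogenes carried most of the counts of their families. TECR, the parent of TECRP1, was at 51.8 ± 7.29 CPM in SR and 67.3 ± 8.98 in FR (n = 6 each). TECR with its copies summed to 57.6 ± 8.47 and 68.2 ± 8.86 CPM. BZW1 with its copies summed to 180 ± 15.5 CPM in SR and 179 ± 16.7 in FR. NUS1 with its copies stayed lower in SR, at 53.6 ± 7.67 against 80.8 ± 8.33 CPM. Libraries marked SR had lower totals, 26.2 ± 5.98 M counts against 33.0 ± 6.23 M (exact permutation p = 0.0779, adjusted 0.468), and thinning all libraries to the lowest total left 67 calls, 59 of them pseudogenes.

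Storage libraries resembled the library with the same number more than those with the same suffix. All 12 had their highest Spearman correlation of log2 CPM with their own number (exact permutation p = 0.00139), at 0.9915 to 0.9924 within pairs against 0.9653 to 0.9829 otherwise. All 8 cryopreservation libraries did so too (exact permutation p = 0.0417), at 0.9843 to 0.9851 within pairs against 0.9519 to 0.9828. Among the concentration libraries, 5 of 6 were closest to a library with their own column letter, at 0.9905 to 0.9922 within a letter against 0.9891 to 0.9919 otherwise. All concentration libraries thus correlated more closely (0.9891 or above) than storage libraries with different numbers (0.9829 or below). They may be repeats from 1 sample, which the labels did not state.

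Libraries with the suffix f carried more transcripts of B cell genes than CD4+ T cell libraries without it. PAX5 (ENSG00000196092, chromosome 9, 36833275 to 37034185), the transcription factor that maintains B cell identity, rose to 8.81 ± 2.90 CPM from 0.196 ± 0.196 (SD, n = 4 each; log2 change 5.44, SE 0.57, edgeR adjusted p = 0.0326). CD22 (chromosome 19, 35319261 to 35347355), an inhibitory receptor of B cells, rose to 11.6 ± 6.51 from 0.859 ± 0.246 CPM (3.75, SE 0.44, edgeR adjusted p = 0.0387). RIMBP3C, 1 of 3 near-identical genes, rose to 4.51 ± 1.32 from 0.0985 ± 0.0781 CPM (5.43, SE 0.56, edgeR adjusted p = 0.0326), and the 3 RIMBP3 genes summed to 5.33 ± 1.26 and 1.69 ± 0.519 CPM. FOSB and JUN, transcription factors induced within minutes of a stimulus, were at 61.2 ± 42.8 against 4.91 ± 2.25 and at 194 ± 155 against 18.3 ± 10.1 CPM. For JUN, f replicate 2 was at 423 CPM, and the mean without it was 118. For PAX5, the mean without the suffix was 0.0999 CPM when replicate 4 was left out. Transcripts of the mitochondrial genome took 8.31% ± 5.25 of the counts with f and 2.99% ± 0.360 without (exact permutation p = 0.0286, adjusted 0.0857; paired exact p = 0.125, the lowest that 4 pairs allow), with f values of 4.96%, 5.30%, 6.89% and 16.1%.

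Without a block, edgeR called 7 of 18654 genes, 7 higher and 0 lower in f, with 1681 at an unadjusted p under 0.05, while DESeq2 called 198 (116 higher, 82 lower) and limma-voom 1. The other calls, chosen after their values were seen, were OSBPL10 (2.61 ± 0.784 against 0.447 ± 0.0705 CPM, log2 change 2.53), COL19A1 (1.22 ± 0.324 against 0.102 ± 0.0590 CPM, 3.53) and 2 immunoglobulin genes. With the pair as a block edgeR called 54 genes, 47 higher and 7 lower in f, and the biological coefficient of variation went from 30.1% to 15.4%. The balance of directions depended on the program: with the block, DESeq2 called 642 (321 higher, 321 lower) and limma-voom 59 (51 higher, 8 lower). Leaving out replicate 1, 2 or 3 took the unblocked count to 0 each time (1251, 1011 and 1024 genes at an unadjusted p under 0.05 in edgeR) and the blocked count to 248, 16 and 32. Without replicate 4, the library highest in mitochondrial transcripts, they were 8 and 50. Among protein-coding genes alone, an alternative added after the data were seen, edgeR called 0 genes without the block (1368 at an unadjusted p under 0.05) and 32 with it.

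In the blocked fit FCRL5 and FCRL2, receptors of the Fc receptor-like family on B cells, rose by 4.76 and 3.39 log2 units (edgeR adjusted p = 0.00199 and 0.0135). MS4A1 (the antigen CD20) and BANK1 rose by 3.23 and 2.76 (edgeR adjusted p = 0.00324 and 0.00777), all in 4 of 4 pairs. FOSB and JUN rose by 3.46 (SE 0.37) and 3.32 (SE 0.41), with edgeR adjusted p = 0.00777 and 0.0145 against 0.116 and 0.252 without the block. HBB, the beta chain of haemoglobin, fell, at 0.224 ± 0.265 CPM with f and 18.7 ± 25.8 without (blocked edgeR adjusted p = 0.0103), a level without f set largely by replicate 3 at 57.3 CPM (mean of the others 5.83; with f, 0.0956 without replicate 4). CLTC, the clathrin heavy chain, fell from 213 ± 17.8 to 150 ± 17.1 CPM (-0.51, SE 0.06, blocked edgeR adjusted p = 0.0155). SPTLC2 belongs to the enzyme that starts sphingolipid synthesis and ATP6V1A to the vacuolar proton pump. Together with DCAF7 and ABHD2 they fell, in the order DCAF7, SPTLC2, ABHD2 and ATP6V1A, by 0.62, 0.54, 0.50 and 0.50 on the log2 scale (blocked edgeR adjusted p = 0.0377, 0.0405, 0.0440 and 0.0490).

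**Figure D3:**
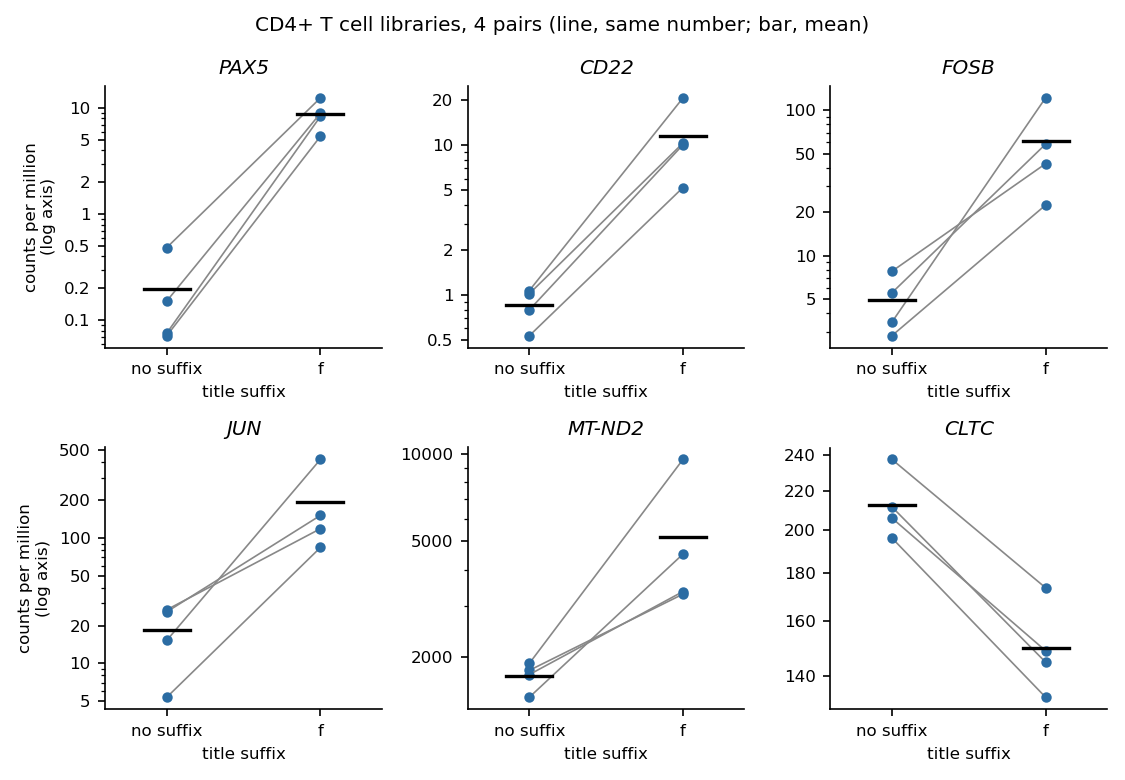
CPM (vertical log axes) of 6 genes in CD4+ T cell libraries without and with the suffix f (horizontal axis); each line joins the libraries with the same number (4 pairs) and thick bars are means. PAX5, CD22, FOSB, JUN and MT-ND2 are higher with f in every pair and CLTC is lower in every pair.

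By group, 18 of 20 tested B cell genes had a log2 change above 0 in f (median 2.26, camera adjusted p = 9.29e-20), although adjusted p = 0.273 with an estimated correlation. Of these, 2 rose over all genes and 13 when adjusted over the list alone, and with the block 11 and 16 did. CD79A, part of the B cell receptor, was at 13.0 ± 6.60 against 2.32 ± 0.331 CPM (blocked log2 change 2.39, edgeR adjusted p = 0.00346). The mitochondrial genome list had a median of 1.59 (camera adjusted p = 2.33e-16; adjusted p = 0.273 with an estimated correlation), with 0 of 13 members called over all genes, 13 adjusted over the list alone and 1 over all genes with the block. MT-ND2, MT-CO2, MT-ND1 and MT-ND6 were at 5194 ± 2992, 6847 ± 4477, 4861 ± 3284 and 2279 ± 1354 CPM with f and at 1721 ± 192, 2132 ± 175, 1487 ± 192 and 795 ± 73.6 without, in a group where f replicate 4 stood far above the others (mean of MT-ND1 without it 3236 CPM). MT-ND6, encoded on the light strand, was the member called with the block (1.36, SE 0.21, edgeR adjusted p = 0.0483).

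The immediate early list had a median of 0.46 over 28 genes (camera adjusted p = 9.64e-08; adjusted p = 0.517 with an estimated correlation). None of its members rose over all genes in the unblocked edgeR fit, 6 rose adjusted over the list alone, and with the block 3 (FOSB, JUN and RGS1) and 12 did. RGS1, a regulator of G protein signalling, was at 30.9 ± 21.6 against 6.67 ± 1.96 CPM (20.3 with f without replicate 2), and CCNL1 at 565 ± 52.5 against 420 ± 40.9 CPM. Platelet genes had a median of 1.84 over 8 members (camera adjusted p = 2.25e-06; adjusted p = 0.273 with an estimated correlation), with 0 called over all genes and 5 adjusted over the list alone. ITGA2B, CAVIN2 and SPARC were at 1.45 ± 1.19, 1.92 ± 1.67 and 1.76 ± 1.61 CPM with f and at 0.140 ± 0.0926, 0.147 ± 0.138 and 0.245 ± 0.103 without. Replicate 4 set the levels with f: without it ITGA2B, CAVIN2 and SPARC had means of 0.876, 1.09 and 0.960 CPM. Without the suffix, CAVIN2 was at 0.0947 CPM when replicate 3 was left out.

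Nuclear genes of oxidative phosphorylation had a median of 0.14 over 46 members (camera adjusted p = 1.88e-06; adjusted p = 0.273 with an estimated correlation), with 0 members called, among them COX6B1 at 68.6 ± 4.47 against 56.8 ± 4.32 CPM, NDUFA2 at 25.9 ± 0.357 against 21.1 ± 2.00 CPM, ATP5MC1 at 22.8 ± 1.83 against 18.2 ± 1.59 CPM and NDUFS1 at 68.8 ± 3.54 against 81.6 ± 5.17 CPM. Of the other lists, cytotoxic CD8 and NK genes (median 0.56, camera adjusted p = 9.13e-05), ribosomal protein genes (0.12, 5.78e-05) and inflammatory NF-kB genes (0.30, 0.0217) were higher, with adjusted p = 0.273, 0.773 and 0.595 with an estimated correlation. Erythroid (median -6.46 over 3 genes, camera adjusted p = 0.00273), heat shock (-0.20, 0.00308) and neutrophil genes (-0.69, 0.0178) were lower, with adjusted p = 0.290, 0.273 and 0.626 with an estimated correlation. T cell identity genes such as CD3E (22 tested) had a median of 0.00 (camera adjusted p = 0.971), and monocyte genes such as LYZ a median of -0.18 (camera adjusted p = 0.192). With the block 7 further lists passed camera. Monocyte (blocked median -0.319, adjusted p = 0.00735), naive T cell (-0.145, 0.00909) and interferon response genes (-0.120, 0.0243) were lower in f. Plasma cell (0.233, 0.00257), memory and effector T cell (0.199, 0.0206), replication-dependent histone (0.277, 0.0382) and splicing genes (0.086, 0.0431) were higher. For these 7 the adjusted p = 0.344 to 0.717 with an estimated correlation. With the block, fry called 3 lists, B cell identity and cytotoxic genes (both adjusted p = 0.0216) and replication-dependent histones (adjusted p = 0.0310), all higher in f. No list of the 31 held with an estimated correlation, with or without the block.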

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

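The tests of shared reads, of other cytokine genes with IL24 left out, of transcripts with AU-rich elements and of a lower CD4+ share were chosen after the results were seen. Of 124 groups of 4 to 6 libraries checked for a library far from the rest, 12 held one, where chance gives about 5%. In the SR group, replicate 6 stood apart for BTF3P3 (3.291 CPM, nearest other 2.151), EEF1A1P4 (15.43, 2.393) and IFNG (0.9825, 1.237), and replicate 4 for RPL29P26 (8.16, 1.277). In the FR group, replicate 6 stood apart for EEF1B2P6 (4.751 CPM, nearest other 1.858). With the suffix f, replicate 2 stood apart for CCNL1 (642.8 CPM, nearest other 546), and replicate 4 for MT-ND1 (9734, 3819), MT-ND6 (4298, 1794), SPARC (4.164, 1.246) and the number of genes with at least 1 count after thinning (28567, 28006). Without the suffix, replicate 3 stood apart for FCRL2 (1.141 CPM, nearest other 0.394) and HBB (57.29, 6.911).

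Pseudogenes such as TECRP1 and BZW1P2 made up 82.95% of the calls between SR and FR without the block and 48.08% with it, where 187 of 443 calls were protein coding. The tables argue against depth, since 88.06% of the calls were pseudogenes after thinning to the lowest total, and against genomic DNA, since the summed counts of 376 olfactory receptor genes had a log2 ratio of 0.064 (95% interval -0.11 to 0.257; exact sign-flip p = 0.5625), far below the median of 1.43 of the rising pseudogenes. Reads shared with parent genes stay open as a candidate explanation: of 57 parents, 43 (75.44%, 95% interval 62.2% to 85.9%) moved against their pseudogene (exact binomial p = 0.000154). A difference in alignment or read length between the groups could shift reads in this way, but neither was given in the sources used here, and no biological explanation was tested.

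IL2 and IFNG were lower in SR than in FR in 6 of 6 pairs each. A general loss of unstable transcripts stays undecided: 12 other transcripts with AU-rich elements, FOS and MYC among them, had a median blocked log2 change of -0.02 (SD 0.088), but that list leaves out NR4A3, EGR2 and NR4A1, which fell with the block (-2.47, -0.91 and -0.42). Reads from libraries of stimulated T cells may have entered the FR libraries: the sum of 10 other cytokine genes was higher in FR in 2 of 6 pairs (exact sign-flip p = 0.5312), a sum set by IL24 at 60.4 to 89.2 CPM, and in 6 of 6 pairs with IL24 left out (1.55 against 2.39 CPM, exact sign-flip p = 0.0312, the smallest that 6 pairs allow). Stimulated cells in the FR samples themselves would give the same values and were not tested. Scaled by library totals, IL2 was at 4.89 ± 1.11 CPM with the suffix f and 5.27 ± 2.01 without it. It was at 3.94 ± 1.61 CPM in FR, 0.493 ± 0.571 in SR and 0.087 in SRN. IFNG was at 2.77 ± 0.974 and 2.30 ± 1.07 CPM with and without f, 2.94 ± 0.502 in FR and 1.25 ± 0.126 in SR. The cryopreservation libraries were thus nearer FR than SR, and a gain in FR was not told apart from a loss in SR.

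B cell genes were higher with the suffix f. Markers of other cell types did not all rise with them. Monocyte and neutrophil genes had median blocked log2 changes of -0.319 and -0.743 where B cell genes had +2.30 (permutation p = 0.00018 and 0.00727 over genes). The medians of cytotoxic and platelet genes were above 0 (0.569 and 1.72, with permutation p = 0.00045 and 0.839 against B cell genes). Whether the share of CD4+ T cells was lower stays undecided, because other cell types need not change alike. B cells, or RNA from them, may have been present in the samples with f: across 20 B cell genes, the gain in f followed the level in the B cell libraries of this series (Spearman rho 0.854, 95% interval 0.563 to 0.967; permutation p = 1e-05, the smallest that 100000 permutations give), at a median of 0.803% of that level. By library the median level was 0.7185%, 0.9404%, 0.9935% and 2.032% in f replicates 1 to 4, in the order of their mitochondrial shares (4.96%, 5.30%, 6.89% and 16.1%). Without f it was 0.1667%, 0.1981%, 0.3853% and 0.7132%, and the mitochondrial shares (3.04%, 3.06%, 2.49% and 3.35%) did not keep that order. By this median, replicate 4 without f came close to replicate 1 with it. The B cell genes named above were all lower in replicate 4 without f than in replicate 1 with it. PAX5 was at 0.486 against 5.43, CD22 at 1.075 against 5.23 and MS4A1 at 6.31 against 19.9 CPM (TMM scaling). The percentages were scaled by the total of each library. Reads carried over from the B cell libraries would also give a gain that follows their level, and were not tested.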

How the results depend on the processing

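The letter term, the restriction to protein-coding genes, and the combined settings with a letter, a block and a further threshold were chosen after the data were seen. Named genes kept direction in every setting tried: 396 comparisons for SR against FR kept their side of the threshold, 49 became stronger and 29 weaker, against 388, 55 and 7 for concentration 1 against 500, 70, 0 and 4 for 100 against 500, 14, 0 and 2 for the slope, and 421, 137 and 19 for f against no suffix. The cause of the differences below was not tested, except that fewer genes or libraries were tested where the setting says so.

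For concentration 1 against 500 (5 genes), edgeR called 133 with the letter, 32 with no filter, 2 among protein-coding genes, 464 with the letter among protein-coding genes and 15 with the letter at an absolute log2 change of at least 1, DESeq2 called 16, limma-voom 2, and leaving out 1 library gave 7 to 11. For 100 against 500 (6), no filter gave 23, limma-voom 3, protein-coding genes 2 and leaving out 1 library 5 to 11. For 1 against 100 (0), the letter gave 5, no filter 12, DESeq2 5, the letter with protein-coding genes 4, the letter at a log2 change of 1 gave 3 and leaving out 1 library 0 to 5. For the slope (1), the letter gave 33, no filter 7, DESeq2 6 (F8A2 not among them), limma-voom 0 (1272 at an unadjusted p under 0.05), the letter with protein-coding genes 216, the letter at a log2 change of 1 gave 6 and leaving out 1 library 1 to 10. Counts moved by over 1.5 times without either library at 1 or at 500 (1 against 500: 10, 11, 10 and 9; slope: 10, 6, 2 and 3; 1 against 100: 5, 3, 1 and 1), and without a library at 100 (letter c: 11 for 100 against 500, 4 for 1 against 100; letter d: 2 for the slope). A lone library was assumed to vary like the other groups. No paired analysis was possible because the replicate numbers of the titles could not be matched to the concentration columns. The fit with the letter is a block on a column letter whose meaning was not given. Also, 250 against 500 was not run, and 250 was left out of the slope. The labels gave 1 sample at 250 where the table held 2 columns, and these columns were left unmatched. That was a choice, since 100 was used with 3 labelled samples and 2 columns.

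For SR against FR (88), the block gave 443, a mean count of at least 50 gave 48, DESeq2 139, the block in DESeq2 325, the block in limma-voom 536, protein-coding genes 5 and 194 with the block, a log2 change of at least 1 with the block 114, and leaving out 1 pair 62 to 71, or 331 to 390 with the block. For f against no suffix (7), the block gave 54, library size alone 11, no filter 18, a mean count of at least 50 gave 3, DESeq2 198, limma-voom 1, thinning 4, the block in DESeq2 642, the block in limma-voom 59, protein-coding genes 0 (1368 at an unadjusted p under 0.05 in edgeR) and 32 with the block. Leaving out 1 pair gave 0 to 8, or 16 to 248 with the block. PAX5 and RIMBP3C lost their calls without replicate 1, 2 or 3, in limma-voom and among protein-coding genes, and RIMBP3C also without replicate 4. CD22 lost its call in all of these, after thinning and at a mean count of at least 50.

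Gene lists past the threshold numbered 3, 2, 1 and 3 for 1 against 500, 100 against 500, 1 against 100 and the slope, 1 for SR against FR and 11 for f. With an estimated correlation, and with fry, each of these was 0. The letter gave 3 for 1 against 100, and 0 in each concentration comparison with an estimated correlation or fry, except 1 for the slope with fry. The block gave 7 for SR against FR (0 with an estimated correlation, 0 with fry) and 18 for f (0 and 3). The biological coefficient of variation was 9.28% (5.06% with the letter), 8.56% for the slope (5.28%), 28.2% for SR against FR (5.17% with the block; 26.2% to 29.7% and 4.61% to 5.29% without 1 pair) and 30.1% for f (15.4%; 25.4% to 31.1% and 13.4% to 16.7%). Numbers of genes detected reversed with depth: at least 10 counts, SR minus FR was 88.8 after thinning and -727.2 as deposited, and f minus no suffix was -129.2 and 257.5. At 1 count the latter was -57.2 and 222.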

Other observations

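All genes named in this part, apart from IL2, NUS1, HBB and PHC1P1, were chosen after their values were seen. In libraries with the suffix f, the list of cytotoxic genes passed camera with the pair as a block (adjusted p = 1.95e-10; adjusted p = 0.167 with an estimated correlation). NKG7 was at 23.6 ± 8.89 against 12.1 ± 5.28 CPM (SD, n = 4; blocked log2 change 0.99, edgeR adjusted p = 0.00552), KLRD1 at 5.45 ± 3.49 against 1.88 ± 0.815 CPM (1.45, 0.0372) and GNLY, a protein of cytotoxic granules, at 26.8 ± 8.06 against 12.4 ± 6.98 CPM (1.23, 0.0469). These were the 3 of 18 cytotoxic genes called with the block over all genes, and 11 were called when adjusted over the list alone. HBA2, the alpha chain of haemoglobin, fell with HBB (blocked edgeR adjusted p = 0.0120). It was at 0.0217 ± 0.0434 CPM with f, counted in replicate 4 alone, and at 2.28 ± 2.56 without the suffix (0.998 without replicate 3). IL2 was at 5.04 ± 1.12 CPM with f and 5.11 ± 1.93 without (edgeR adjusted p = 0.998).

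Between SR and FR, 4 of 28 immediate early genes fell and 0 rose in the blocked edgeR fit, and the list's median with the block was near 0 (-0.015). NR4A3, a nuclear receptor, was at 0.347 ± 0.378 against 1.80 ± 0.692 CPM (SD, n = 6; blocked log2 change -2.47, edgeR adjusted p = 0.00120; SR mean 0.230 without replicate 3), and NR4A1 (-0.42, 0.0186), EGR2 (-0.91, 0.0471) and ZFP36 (-0.09, 0.0356) also fell. The immediate early list of 28 genes passed camera with the block (adjusted p = 0.0308, against 0.913 without it; adjusted p = 0.286 with an estimated correlation). Of 13 mitochondrial genes, MT-ND2 and MT-CO1 fell with the block (-0.23 and -0.20, edgeR adjusted p = 7.98e-05 and 0.000388) and MT-ND3, MT-ND4 and MT-ND5 rose (0.09, 0.03 and 0.03). Of 77 ribosomal protein genes, 13 rose and 6 fell with the block.

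The library marked SRN was in no comparison. Its Spearman correlation was 0.9915 with SR replicate 4, 0.9894 with FR replicate 4, and 0.9661 to 0.9781 with the others. Scaled by library totals, TECR was at 40.5 CPM, NUS1 at 50.7, PHC1 at 13.2 and PHC1P1 at 18.5 in it. In SR replicate 4 they were at 47.4, 53.7, 17.9 and 21.8 CPM, and in FR replicate 4 at 58.1, 89.6, 51.8 and 3.83 CPM.

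Other splits of the libraries were counted for each comparison of at least 3 libraries per group. For SR against FR, 3 of 100 splits drawn from 462 gave at least the real 88 genes, a share of 3%, under 0.05, although its 95% interval of 0.623% to 8.52% reached above it. The highest other split gave 603, which points to a structure of the samples: the other splits as large parted no pairs, and the highest of the 4 other splits that parted every pair was 0. With the block, 1 of 32 splits, the real one, gave 443 genes, and the highest other gave 9, so chance was excluded at 0.05. For f against no suffix, 4 of 35 splits gave at least 7 genes and the highest other gave 301, so chance was not excluded without the block. The other splits as large parted no pairs, and the highest of the 7 others that parted every pair was 1. With the block, 8 splits were too few for a share under 0.05, with 54 genes in the real split and 0 in the highest other.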
